A study of Mus musculus with 2 samples.

How the data were processed

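Total RNA depleted of ribosomal RNA was sequenced from the chromatin fraction of mouse bone-marrow-derived macrophages, in 2 libraries of 1 group. Per the labels, the libraries were biological replicates 1 and 2 of the same treatment, started from 250 and 500 ng of RNA, and both carried the same donor entry. The spread between them is therefore the spread between 2 samples whose separate cultures the labels do not spell out.

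The deposited expected counts per gene and per transcript came from alignments of each library to the mm10 transcriptome with the GENCODE M21 annotation, per the submitters' description files. Their column names are those that RSEM writes, per the file headers, while the program and its version are not given in the sources used here. The deposited TPM values, which give each transcript's share of the library, were divided by effective length by the authors and scaled to a fixed sum over all entries, spike-in and numbered entries included. The deposited estimated counts of a second transcript table were made directly from the reads without an alignment, with column names that kallisto writes, per the file headers. These tables are called the alignment-based and the alignment-free program here. The alignment-based gene table was the main source, and the alignment-free transcript values were summed per gene. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart.

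Gene names, classes, strands and coordinates were taken from the matching annotation release, which held 55536 of the gene entries. Left out of tests and library sizes were 96 spike-in entries of the ERCC mix, the phiX174 entry and 26248 numbered entries without gene names. The numbered entries held 21 of 18445009 expected counts in replicate 1 and 14 of 17686824 in replicate 2. All 317 symbols of the 22 gene lists matched, and 2 symbols with a pair of gene identifiers (Aldoa and Rmrp) took the lower Ensembl number. Where reads could belong to several entries, the deposited posterior SD of the count was compared with the count. Among 7831 genes with a mean of at least 100 counts, 66 had a posterior SD over 10% of the count, 21 of them protein coding.

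With 1 group and no contrast between conditions, the results are levels and their spread, and no test of a treatment was made. The level of a list was the median over its members of the mean TPM, and its SD was taken between the medians of the 2 libraries. Its percentile was taken among 10000 random lists of the same size, on log2(TPM + 0.1), drawn from the 9615 protein-coding genes at 1 TPM or more in either library. Such a percentile describes these libraries and is no p-value, and lists of silent genes fall to its lower end by construction. Replicates were compared across genes on log2(TPM + 1), and by the log2 ratio of replicate 2 over replicate 1 of rounded expected counts scaled by TMM (edgeR 4.0.16), in genes with at least 10 counts in each library. A 2-sided exact binomial test on the rounded counts, with Benjamini-Hochberg adjustment at 0.05 and a 2-fold minimum, compares those libraries, not the conditions. A second test of the same counts, edgeR's exact test, used the common dispersion of the same 2 libraries, with 1 on each side. The shift of a list was the median log2 ratio of its members, set among 10000 random lists matched on mean count in 20 bins. Shares of counts of a single library carry 95% Wilson intervals. A count of 0 allows up to 3 counts, or 1.63e-05% of replicate 1 and 1.70e-05% of replicate 2. Intervals and limits cover counting error only, since the reads carry no molecular identifiers in the files.

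The steps were tested on simulated data. In 2 libraries simulated with counting noise alone, the model that the binomial test assumes, that step was run on 13498 genes. It recovered 100% of 200 genes changed 4-fold and called 2 of 13298 unchanged genes. Spread between real replicates beyond counting noise was not in that simulation, so 2 of 13298 is no error rate for the real libraries. In 2 other simulated libraries with added spread, the common biological coefficient of variation (BCV) was estimated as 0.198 where 0.2 had been simulated. Of 400 unchanged lists of 15 genes, 5.25% fell outside the central 95% of random lists in the shift step on 13247 genes, and 5.75% in the level step. These lists were random draws of independent genes, so such shares follow from their construction. Lists of genes that vary together, as real lists may, were not simulated.

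Genes named in the text follow, unless marked as picked after their values were seen, a rule set before the data were examined, together with the lists and the comparisons. Named were the 4 highest and the lowest member of each list by mean TPM, the 15 protein-coding and 10 long noncoding genes of highest mean TPM, and the 10 protein-coding genes with the largest ratio each way at a mean of at least 100 counts. The rule also took list members over 2-fold apart at that count, the 10 genes on which the programs differed most at 10 TPM or more, and the 10 protein-coding genes at 10 TPM or more with the largest retained-intron share. Alternatives to these choices covered the other program, DESeq2 size factors (1.42.0) or library size, filters, pseudocounts, random lists from all protein-coding genes, TPM over protein-coding genes and the omission of each replicate. Other steps ran in R 4.3.3 and in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.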

Results

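Bone-marrow-derived macrophages, phagocytes grown from the marrow of C57BL/6J mice, were exposed to lipid A, the membrane anchor of bacterial lipopolysaccharide that activates Toll-like receptor 4 (TLR4). The cells received 100 ng/ml lipid A for 12 h, were washed out for 12 h and received 100 ng/ml again for 75 min. RNA bound to chromatin, a fraction that holds transcripts still being made, was depleted of ribosomal RNA and sequenced in 2 biological replicates of this 1 condition. Replicate 1 had 18445009 expected counts and replicate 2 had 17686824, of which 18388793 and 17640464 fell on annotated genes. At least 1 TPM was reached in both libraries by 11567 genes, of which 8829 were protein coding, 1047 long noncoding and 1691 of other classes. Samples without the second exposure or without any were not analysed here, so the values below are levels in restimulated cells. Errors are SDs with n = 2, for lists the SD between the medians of the libraries, coordinates are in mm10, and percentiles of lists refer to random lists of expressed protein-coding genes, whose median level was 7.99 TPM.

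The first question was which programmes of the macrophage were transcribed at the time of the second exposure. Interferon-response and NF-kB genes, which carry the transcriptional answer to TLR4, lay far above expressed genes in general. All 20 members of the interferon list reached 1 TPM in both libraries and 13 reached 100 TPM, with a list median of 189.7 ± 18.7 TPM. All 16 members of the NF-kB family and feedback list reached 10 TPM, with a median of 199.0 ± 31.5 TPM, and both lists exceeded each of 10000 random lists. With TPM taken over protein-coding genes alone the medians were 700.7 and 737 TPM. That choice multiplies lists and random lists of a library by the same factor, so it does not test their rank. The antiviral genes Mx1 (903 ± 217 TPM), Rsad2 (646 ± 281) and the guanylate-binding protein Gbp5 (613 ± 150) led the interferon list together with Stat2 (386 ± 24.0), which transmits interferon signals. At its lower end was the interferon gene Ifnb1 itself, at 2.61 TPM in replicate 1 and 14.4 TPM in replicate 2. In the NF-kB list the feedback inhibitors Tnip3 (653 ± 133 TPM) and Tnfaip3 (419 ± 171) stood beside the subunit gene Nfkb1 (488 ± 143) and the adaptor Traf1 (335 ± 61.4), while the deubiquitinase Cyld was lowest at 15.8 ± 2.97 TPM.

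Chemokine genes were also high as a group, at a median of 89.3 ± 40.1 TPM and above every random list, but their members ranged widely. Ccl5 (chromosome 11, 83525778 to 83530518), which attracts T cells and monocytes, reached 832 ± 133 TPM, followed by Ccl4 at 214 ± 75.0, Cxcl10 at 208.9 ± 8.99 and Cxcl2 at 166 ± 27.7 TPM, whereas Cxcl9 had 1 and 3 counts. Inflammatory cytokines and mediators as a list were not set apart, with a median of 10.5 ± 6.89 TPM (6.77 without replicate 2 and 16.5 without replicate 1) at the 70.8th percentile and 10 of 15 members at 1 TPM in both libraries. Within it Tnf (chromosome 17, 35199381 to 35202007) stood at 436 ± 67.7 TPM, Il1b at 169.8 ± 70.8, Il1a at 128 ± 56.6 and Il18 at 32.0 ± 1.36, while the growth factor gene Csf3 had 4 counts in each library. The percentile of this list was 31.1 in replicate 1 alone, 90.6 in replicate 2 alone and 98.7 by the alignment-free program, which set it apart. Immediate early genes, the first wave of transcription factors and their regulators, had a median of 11.5 ± 2.14 TPM at the 76.9th percentile. Their highest members were Klf6 (203 ± 45.4 TPM), the phosphatase gene Dusp1 (95.8 ± 66.5), Atf3 (61.8 ± 27.0) and Junb (60.5 ± 3.22), and the lowest was Fosb at 0.40 ± 0.297 TPM.

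Negative regulators of TLR signalling were transcribed at a median of 49.0 ± 6.40 TPM, at the 99.98th percentile. Acod1, which makes itaconate from a citric acid cycle intermediate, reached 1158 ± 144 TPM, ahead of Tnfaip3, the inhibitor of NF-kB Nfkbia (301 ± 95.2 TPM) and Tnip1 (226 ± 30.05), and Sigirr had 1 count in replicate 1 and 0 in replicate 2. The TLR4 pathway had all 21 members at 1 TPM in both libraries and a median of 24.8 ± 4.50 TPM at the 99.7th percentile, led by the kinases and adaptors Irak2 (233 ± 1.15 TPM), Tbk1 (223 ± 17.7), Ikbkb (182 ± 54.8) and Tab2 (76.0 ± 16.9), with Tirap lowest at 2.79 ± 0.332 TPM. Antimicrobial and pattern recognition genes had a median of 23.5 ± 0.757 TPM at percentile 94.3 (98.4 with TPM over protein-coding genes alone), and their members were divided. The C-type lectin receptors Clec4e (670 ± 104 TPM) and Clec4d (139 ± 52.8), the acute-phase gene Saa3 (360 ± 91.8) and the complement gene C3 (146 ± 12.7) were high, and haptoglobin (Hp) had 1 count in replicate 1 and 0 in replicate 2. Genes of macrophage metabolism had a median of 14.3 ± 3.77 TPM at the 90.7th percentile (97.8 by the alignment-free program), with Acod1, the hexokinase Hk3 (329 ± 2.69 TPM), the cholesterol exporter Abca1 (265 ± 2.71) and the glycolytic regulator Pfkfb3 (53.5 ± 28.5) on top and Arg1 at 3 and 1 counts.

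Macrophage identity genes were transcribed in these libraries, and by the alignment-based program most markers of other marrow or tissue cells were near or at 0. The identity list had 19 of 20 members at 1 TPM in both libraries and a median of 39.1 ± 0.866 TPM at the 99.99th percentile. Adgre1, which encodes the surface marker F4/80, had 345 ± 215 TPM, the scavenger receptor Msr1 279 ± 39.3, the protease gene Ctsb 272 ± 47.0 and the Fc receptor chain Fcer1g 125 ± 8.92, while the transcription factor gene Cebpa was lowest at 0.475 ± 0.00707 TPM. The medians of the B cell, T cell and NK cell, neutrophil precursor and mast cell lists were 0 TPM, that of the erythroid list was 0.0025 TPM, and those of the dendritic and fibroblast lists were 0.168 and 0.225 TPM. Without replicate 1 the last 2 were 0.09 and 0.14 TPM, and without replicate 2 they were 0.225 and 0.15 TPM. These 7 lists lay between percentiles 4.61 and 45.9 of random lists of all protein-coding genes, silent ones included. The B cell list summed to 3 and 2 counts and the neutrophil precursor list to 3 and 5 counts over 10 genes, S100a9 among them with 2 in each library. The highest members of the lists by mean TPM were Cd4, with 68 and 52 counts, the heme synthesis gene Alas2 with 29.1 and 9.36, Hdc with 38 and 82, Zbtb46 with 51 and 52, Col3a1 with 20 and 22, and the B cell marker Ms4a1 with 2 and 1. Gzma, Blk, Tpsb2 and Cd209a had 0 counts in both libraries by both programs. The alignment-free program gave higher values for other markers, with Cd3d at 17.8 TPM against 0.045, Thy1 at 13.2 against 0, Sparc at 5.83 against 0.37, Cxcr2 at 3.56 against 0 and Cd8a at 1.54 against 0.015, genes picked after their values were seen. Its list medians were 0.312 TPM for T and NK cell markers, 0.763 for fibroblast markers and 0.621 for dendritic markers, so the absence of these cells is not shown. Cell-cycle genes were low, with 3 of 14 members at 1 TPM in both libraries and a median of 0.460 ± 0.0672 TPM (1.54 by the alignment-free program), yet Mki67, a proliferation marker, had 81.9 ± 17.9 TPM from 11651 and 14216 counts, while Top2a had 2.23 ± 0.262, Mcm5 1.42 ± 1.56, Mcm2 1.06 ± 0.0778 and Plk1 0.115 ± 0.0354 TPM. When random lists were drawn from all protein-coding genes, including silent ones, 14 lists in place of 9 lay in the top 2.5% of random lists and 0 in place of 8 in the bottom 2.5%, because a list of silent genes lies below any list of expressed genes.

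**Figure D1:**
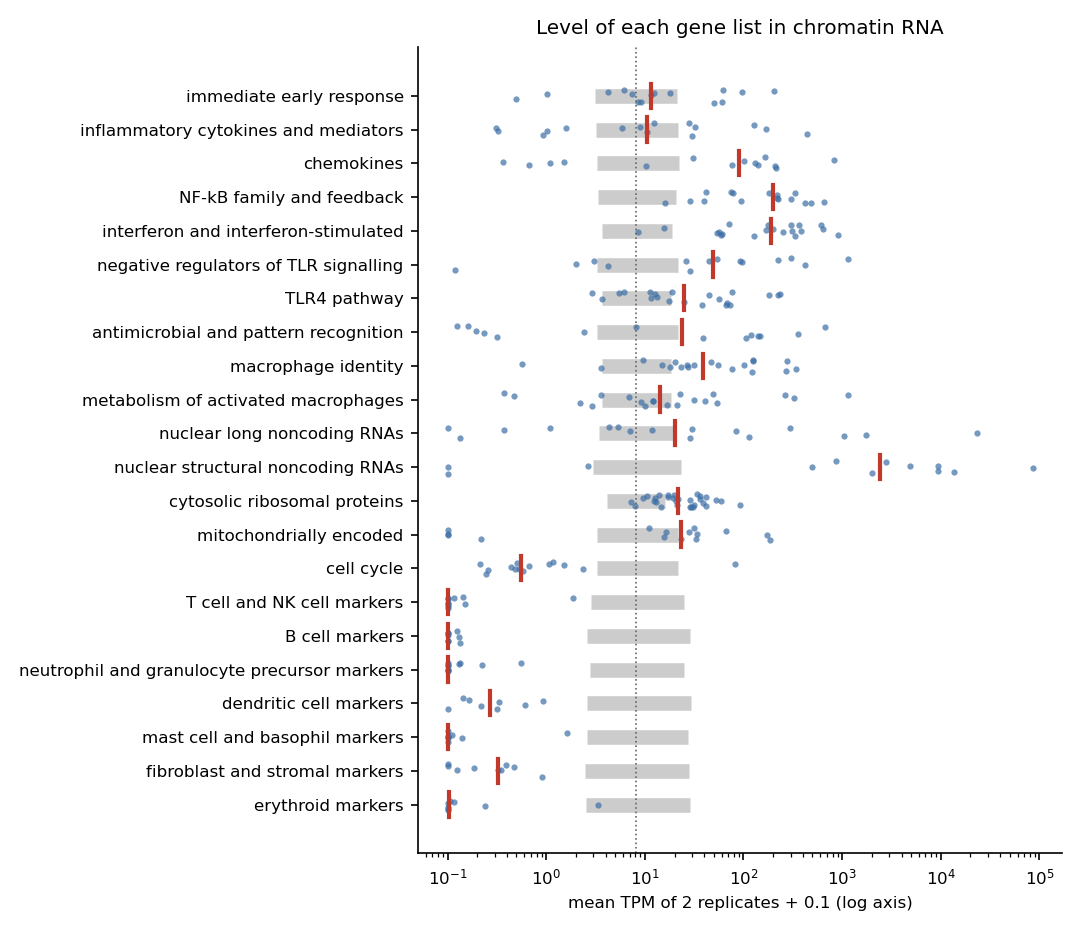
Mean TPM over the 2 replicates, plus 0.1, on a log axis, for each member (blue points) of the 22 gene lists, with the list median (red line), the central 95% of medians of random lists of the same size (grey bar) and the median of expressed protein-coding genes at 7.99 TPM (dotted line). The medians of the NF-kB and interferon lists sit at 199.0 and 189.7 TPM, and those of the 7 lists of other cell types at or below 0.225 TPM.

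The 15 protein-coding genes of highest mean TPM ranged from immune receptors to a splicing factor. The neighbouring immunoreceptor genes Lilrb4a (chromosome 10, 51490956 to 51496611) and Lilr4b (51480632 to 51486703) had 2648 ± 851 and 2121 ± 848 TPM. They were followed by Malt1 (1986 ± 648 TPM, chromosome 18, 65430938 to 65479067), a protease in NF-kB activation, Tnfaip2 (1903 ± 682), the MHC class I gene H2-K1 (1661 ± 158), the kinase gene Ikbke (1390 ± 155) and the transcription factor Zeb2 (1300 ± 280). Acod1, the adaptor Fyb (1131 ± 6.77 TPM), the splicing factor Rbm39 (1104 ± 72.5), Tcirg1 (1017 ± 25.1), Rnf213 (1015 ± 20.7), Sirpa (968 ± 16.9), Parp14 (917 ± 94.7) and Mx1 completed the 15. Lilrb4a was the highest of them in both libraries, at 2046 and 3250.3 TPM.

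Composition by RNA class showed how the reads were divided between protein-coding genes, whose precursor and mature RNA are not separated here, and noncoding RNA. Protein-coding genes held 56.9% of counts in replicate 1 (Wilson interval 56.93 to 56.97) and 58.5% in replicate 2 (58.46 to 58.51). Malat1, a nuclear RNA of speckles, held 7.96% (7.95 to 7.97) and 10.4% (10.43 to 10.45), Xist 1.12% and 1.23%, and Neat1 0.689% and 0.745%. Other long noncoding genes held 1.82 ± 0.176% and mitochondrial genes 0.0402 ± 0.0112% of counts. A further 27.7% (27.64 to 27.68) and 22.8% (22.76 to 22.80) fell on an interval of chromosome 17 that contains the annotated ribosomal RNA gene CT010467.1 (39846353 to 39848827). Most of these reads were assigned to Gm26917 (39843013 to 39846341), annotated as a long intergenic RNA, with 4346717 and 3497299 counts. Gm42418 (39846958 to 39848788) had 530040 and 402410 counts, CT010467.1 on the opposite strand 224380 and 128670, and AY036118 0 in both. RefSeq places the pseudogene Rn18s-rs5 at 39846354 to 39848202 of the same interval, and reads of its overlapping genes could not be told apart.

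**Figure D2:**
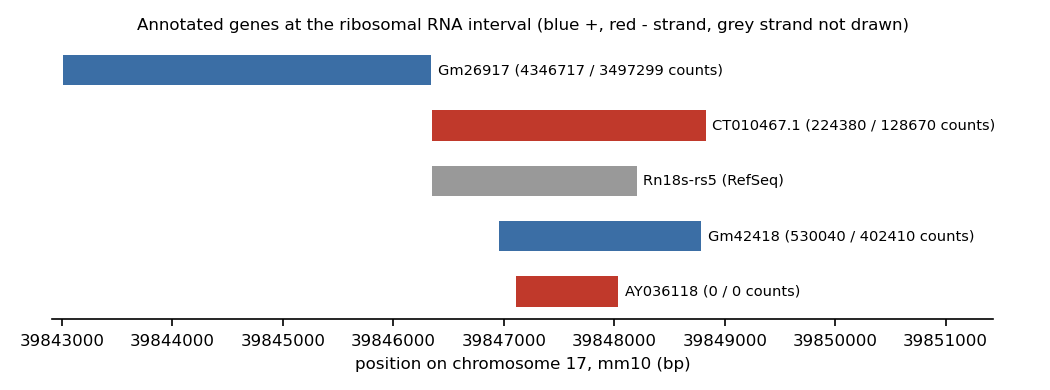
Annotated genes of the chromosome 17 interval in mm10, in base pairs, drawn as bars by strand (blue plus, red minus, grey RefSeq pseudogene) with their expected counts in replicates 1 and 2. Gm26917, with 4346717 and 3497299 counts, lies upstream of the overlapping CT010467.1 and Gm42418.

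By TPM, small structured RNAs dominated instead. Small nuclear, small nucleolar, Cajal body, ribozyme and other structured RNAs took 55.2 ± 0.745% of TPM from 1.26 ± 0.0735% of counts, and protein-coding genes 26.9 ± 1.47% of TPM. Small nucleolar RNAs alone took 27.8 ± 2.68% of TPM from 0.186 ± 0.0209% of counts, and the 114 with counts had a median effective length of 2.21 bases. Of these 114, 112 had under 50 effective bases, as had all 52 small nuclear RNAs with counts. Division by such short lengths turns few counts into large TPM values. Because TPM has a fixed sum, it also lowers the TPM of all other genes, which bears on the 1 TPM limit. In the list of nuclear structural RNAs (median 2413 ± 333 TPM, above all random lists), Rmrp reached 85564 ± 3701 TPM, the transcription regulator Rn7sk 13689 ± 5693, and the identical signal recognition particle copies Rn7s1 and Rn7s2 9475 ± 2245 each, with a posterior SD of 14% of the count, while Snord118 had 0 counts. By the alignment-free program the list median was 1238.8 TPM, Rmrp had 31229, Rn7sk 6068, and Rn7s1 and Rn7s2 4028 each. Snord118 had 84.9 TPM there, from 52 and 54 counts. Nuclear long noncoding RNAs had a median of 20.2 ± 3.04 TPM at the 96.2th percentile (98.7 with TPM over protein-coding genes alone), from Malat1 (23247 ± 6233 TPM), Neat1 (1750.3 ± 150.5), Xist (1041 ± 96.1) and Mir155hg (296 ± 134), the precursor of miR-155, down to Meg3 with 0 counts, or 220 and 237 by the alignment-free program. Gm14636 (707 ± 235 TPM), Gm20559 (430.04 ± 94.5), a second Rmrp entry (16032 ± 9713) and Gm23925, which had 15.7 and 2.74 counts, were the other long noncoding genes of highest TPM beside those of the chromosome 17 interval. Cytosolic ribosomal protein genes had a median of 21.4 ± 1.23 TPM at the 99.7th percentile, between Rpl10 (92.2 ± 11.1), Rpl23 (59.6 ± 14.9), Rpl5 (53.0 ± 1.15), Rps2 (41.6 ± 2.33) and Rpl32 (7.13 ± 1.09). Mitochondrially encoded genes had a median of 23.1 ± 5.95 TPM at the 98.2th percentile (97.3 without replicate 1), led by mt-Co1 (185 ± 61.5), mt-Atp8 (175 ± 56.2), mt-Nd6 (66.7 ± 11.8) and mt-Nd5 (33.7 ± 6.93), and mt-Co2 had 0 counts, or 473 and 0.21 by the alignment-free program.

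**Figure D3:**
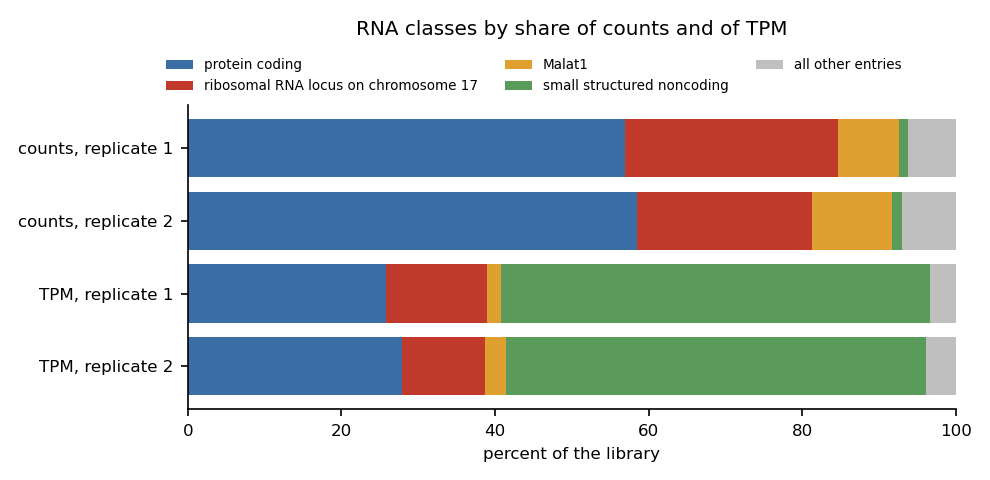
Percent of each library, on a linear axis from 0, in protein-coding genes, the chromosome 17 ribosomal interval, Malat1, small structured noncoding RNAs and all other entries, by expected counts and by TPM for replicates 1 and 2. Small structured RNAs hold 1.21% and 1.31% of counts and 55.7% and 54.7% of TPM.

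Retained-intron isoforms, transcripts annotated as keeping an intron, were assigned a large part of the TPM of protein-coding genes in this fraction. They took 37.7 ± 0.2497% of the TPM of protein-coding genes, against 4.13 ± 0.0167% for isoforms annotated for nonsense-mediated decay and 8.39 ± 0.00485% for processed transcripts without an open reading frame. By counts the retained-intron share was 25.0 ± 0.636%. Of 9283 protein-coding genes at a mean of 1 TPM, 5998 had an annotated retained-intron isoform, their median share was 45.1%, and 2509 genes had over 50%. Among lists with more than 1 protein-coding member at 1 TPM the share was highest for cytosolic ribosomal proteins at 54.0 ± 3.10% and the TLR4 pathway at 49.0 ± 0.562%, followed by chemokines at 47.8 ± 2.36%, the NF-kB list at 45.5 ± 0.474%, antimicrobial genes at 39.98 ± 7.897%, the interferon list at 31.6 ± 0.386% and immediate early genes at 26.1 ± 2.66%. Macrophage identity genes had 21.3 ± 3.45%, negative regulators 18.5 ± 1.18%, inflammatory cytokines 8.87 ± 0.426% and metabolic genes 5.86 ± 0.484%. Only annotated isoforms could receive reads, and 1 of 11 cytokine genes at 1 TPM had a retained-intron isoform against 24 of 30 ribosomal protein genes, so list shares also depend on the annotation. Intron reads of RNA not yet spliced can fall on the same isoforms, so these shares do not separate retained introns from unspliced precursor.

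Single genes had almost all of their TPM assigned to such isoforms. Lilrb4a had 99.4%, Slc27a1 98.6%, Sec11a 98.0%, Ccdc59 97.4%, Map1s 97.4%, Rbm4b 97.1%, Pak1ip1 97.0% and Cops8 95.4%. The ceramide synthase gene Cers6 (chromosome 2, 68861441 to 69114282, 365 ± 100.2 TPM) had 96.2% and the deubiquitinase gene Usp15 (68.0 ± 6.43 TPM) 94.8%. By the alignment-free program Sec11a had 65.7%, Pak1ip1 80.7% and Cops8 83.6%, and by counts Cers6 had 78.8% and Usp15 82.6%. Among the inflammatory genes the shares were spread widely. Tnip3 had 88.3%, Nfkb1 79.5%, Dusp1 90.1%, Clec4e 81.3% and Ccl5 69.8%, whereas Nfkbia had 7.55%. Between these lay, among others, Il1b at 45.6%, Traf1 at 45.3%, Klf6 at 29.6%, Mx1 at 29.4%, Gbp5 at 26.7% and Tnip1 at 25.0%.

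Comparison of the replicates showed higher levels of inflammatory genes in replicate 2, and lower levels of some members of the identity and antimicrobial lists. The secreted interleukin-1 antagonist gene Il1rn (chromosome 2, 24336853 to 24351494) had 160 counts in replicate 1 and 790 in replicate 2, a log2 ratio of 2.43 after TMM scaling. Il6 had a ratio of 1.87, Cxcl1 1.958, Il12b 1.67, Ccl2 1.45, Ccl7 1.32 and Nos2 1.38. In the opposite direction Adgre1 had 16807 and 6321 counts (-1.28), the integrin gene Itgam -1.66, the Fc receptor gene Fcgr1 -1.05 and the scavenger receptor gene Marco -1.70. Lgals3 of the identity list was higher in replicate 2 (1.16, and 0.91 by the alignment-free program). These are differences between 2 libraries of 1 condition.

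Levels in the replicates were correlated across genes. Across 55536 genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.978 and Spearman's rho 0.921. Only 20491 of them had counts in replicate 1 and 20185 in replicate 2. Over 12513 genes with a mean of at least 1 TPM, r was 0.936. The log2 ratio had an SD of 0.549 over 13247 genes with at least 10 counts in each library, and 69.4% of them lay within 0.5. Over 2-fold apart were 960 genes, 532 higher and 428 lower in replicate 2, and with library size in place of TMM the balance turned to 453 higher and 543 lower. The exact binomial test, which compares those libraries and not the conditions, put 904 of the 960 beyond counting noise, 502 higher and 402 lower. Against the spread of all genes between the same 2 libraries, a BCV of 0.232, edgeR's exact test left 34 genes, 28 higher and 6 lower in replicate 2, with 695 at an unadjusted p under 0.05. By the alignment-free program it left 63, 43 higher and 20 lower. With 1 library on each side this only ranks genes by their distance from the common spread.

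**Figure D4:**
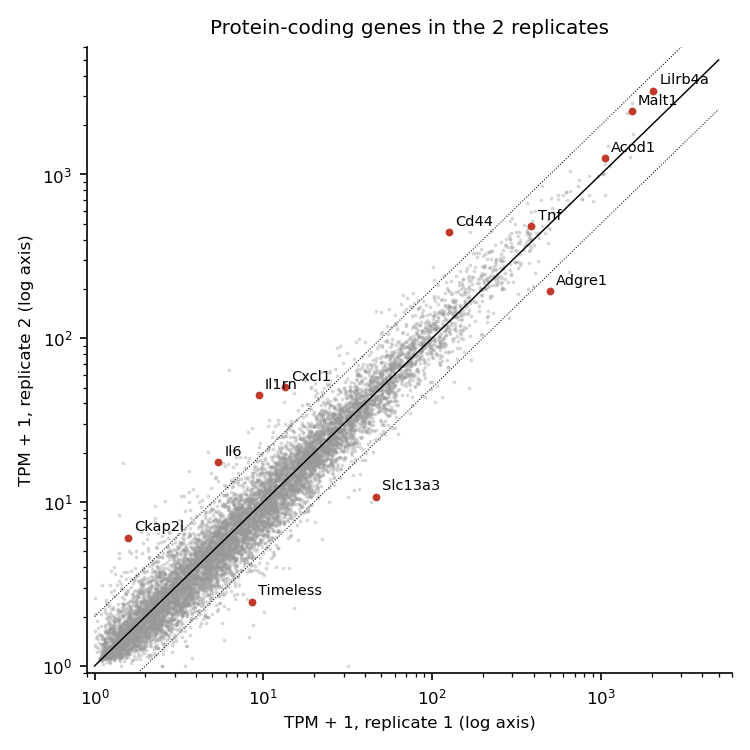
TPM plus 1 of protein-coding genes with a mean of at least 10 counts in replicate 1 (x, log axis) and replicate 2 (y, log axis), with the line of equality and dotted lines at 2-fold. Named genes are in red, among them Cd44 at 126 and 444 TPM and Slc13a3 at 45.6 and 9.80 TPM.

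Among protein-coding genes with a mean of at least 100 counts, those highest in replicate 2 were Ckap2l, a spindle-associated gene (28 and 227 counts, log2 ratio 3.15), Zc3hav1l (2.79), Ndrg1 (2.54), Fam129a (494 and 2538 counts, 2.49), A1cf (2.46), Emp1 (2.44), Il1rn, the phosphatase gene Dusp5 (2.37), the endothelial lipase gene Lipg (2.36) and the cytokine-signalling suppressor Cish (2.33). Those lowest in replicate 2 by the same limits were the carboxylate transporter Slc13a3 (chromosome 2, 165405028 to 165473230, 1344 and 205 counts, -2.59), Sh3bp1 (-2.12), Adam19 (-2.10), Timeless (-2.08), Rims3 (-1.93), Ptp4a3 (-1.90), Heg1 (-1.88), Myb (-1.82), Bmp1 (-1.77) and Gm28048 (-1.72). By the alignment-free program Gm28048, a readthrough gene with a posterior SD of 31% of its count, had -0.15, Myb -0.63, Ptp4a3 -0.94, Heg1 -0.99, Timeless -1.08 and Adam19 -1.50, and among the higher genes Zc3hav1l had 1.12 and Emp1 1.41. Among the 34 genes, and named after their values were seen, were also Cd44 (5154 and 17813 counts, 1.92), Cxcl1, Ifnb1, Il10 and Inhba (2.22), and with lower counts Plagl1 (10 and 87 counts, 3.25), Rcan1 (23 and 150, 2.83) and Nes (116 and 15, -2.82).

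Of the lists, 5 lay higher in replicate 2 than matched random lists, and the identity list did not. These 5 are not independent. The negative regulators share Tnfaip3, Nfkbia and Tnip1, among others, with the NF-kB list and Dusp1 with the immediate early list. Inflammatory cytokines had the largest median log2 ratio, 0.92 with 11 of 12 tested members higher in replicate 2, then chemokines at 0.72 with 12 of 12 and immediate early genes at 0.56 with 13 of 14. The NF-kB list had 0.44 with 14 of 16 and negative regulators 0.37 with 11 of 13. The first 3 exceeded all matched random lists, and the last 2 lay at the 99.8th and 98.7th percentile. The members over 2-fold apart and past the exact binomial test with higher values in replicate 2 were Il6, Il12b, Nos2, Ptgs2 (1.15) and Edn1 (1.76) among cytokines, Ccl2, Ccl7, Cxcl1 and Ccl22 (1.30) among chemokines, Dusp1 (1.58) and Egr2 (1.77) among immediate early genes, and Socs3 (1.05), Il10 (2.46), Il1rn and Dusp1 among negative regulators. Lower were Jun (-1.02) and the phosphatase gene Inpp5d (-1.02). These counts of 5, 4, 2 and 4 higher and 0, 0, 1 and 1 lower were unchanged when adjusted over the list alone. Ccl22 and Il10, with fewer counts than the naming rule asks, were picked after their values were seen, as were Ptgs2os2 and Pdgfrb below. Of these members Cxcl1, Il10 and Il1rn were among the 34 genes furthest from the common spread.

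The interferon list was not set apart, with a median log2 ratio of 0.15 at percentile 67.1, although Ifnb1 (22 and 114 counts, 2.4999) and the RNA sensor Ifih1 (1.31) were over 2-fold higher in replicate 2. The TLR4 pathway had 0.02 with 11 members above and 10 below 0, macrophage identity 0.03 with 11 and 9, antimicrobial genes 0.07, metabolic genes -0.04 and cytosolic ribosomal proteins -0.01, all within the central 95% of matched random lists. The medians of the TLR4 and identity lists were -0.04 and -0.03 with library size in place of TMM. In the metabolic list Pfkfb3 (1.07) and Slc7a2 (1.10) were higher. Nuclear long noncoding RNAs had -0.12 (0.07 by the alignment-free program), with Ptgs2os2 higher (11 and 36 counts), and nuclear structural RNAs 0.11, with Rn7sk (1.04) and Rpph1 (1.24) higher. Mitochondrially encoded genes were lower in replicate 2, with a median of -0.43 at the 0.38th percentile and 8 of 10 members below 0, while the ribosomal RNA gene mt-Rnr1 was higher (1.04). The cell-cycle list had -0.64 at percentile 1.03 over 6 members, Mcm5 (61 and 13 counts) among them. With at least 1 count in each library, or by the alignment-free program, that median was -0.33 or -0.26 and lay at the 11.7th or 3.25th percentile. Dendritic markers had -0.22 over 3 members and fibroblast markers 0.41 over 4, Col1a1 at 15 and 39 counts among them, while the remaining cell-type lists had fewer than 3 tested members. With at least 1 count in each library the dendritic median was -1.04 at percentile 1.7. The fibroblast median was 0.12 by the alignment-free program. By the alignment-free program Slc7a2 (0.86), Pfkfb3 (0.96), Socs3 (0.96), Rn7sk (0.98) and mt-Rnr1 (0.999) were under 2-fold, and with library size the last 4 were as well. For each of these lists the counts over all genes and adjusted over the list alone were the same, except that Pdgfrb (27 and 11 counts) passed only over the fibroblast list alone.

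**Figure D5:**
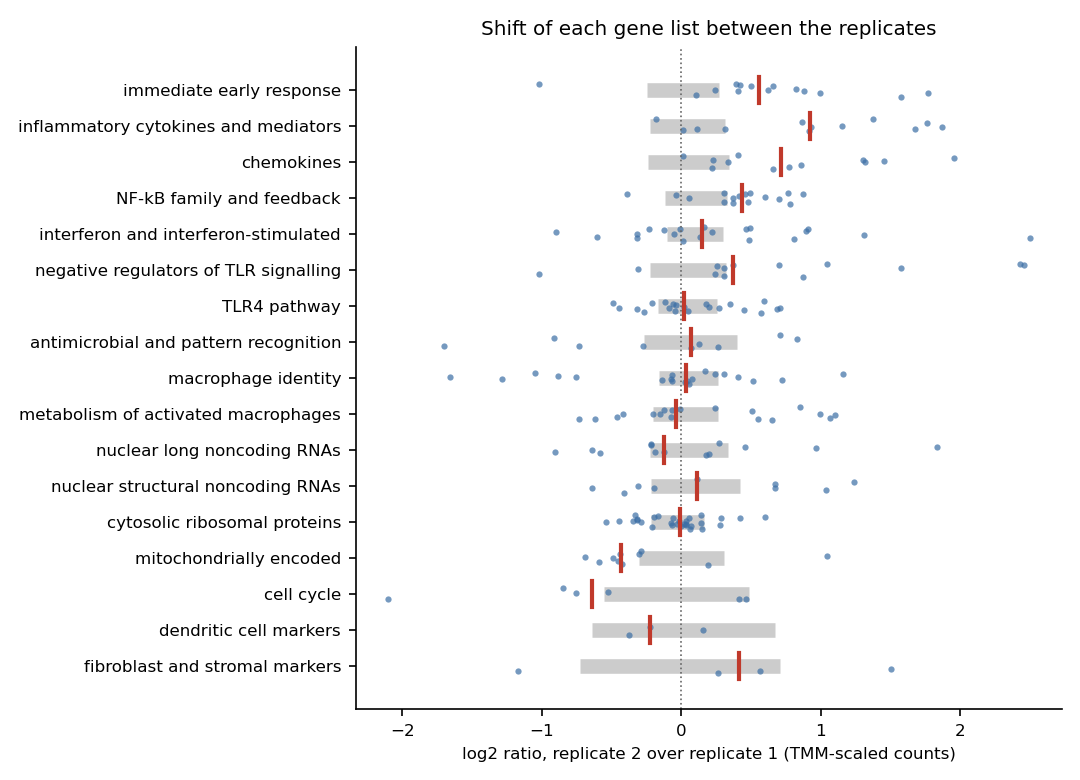
Log2 ratio of replicate 2 over replicate 1 of TMM-scaled counts for each member (blue points) with at least 10 counts in each library, with the list median (red line) and the central 95% of medians of random lists matched on mean count (grey bar). Inflammatory cytokines, chemokines and immediate early genes sit at medians of 0.92, 0.72 and 0.56, and macrophage identity genes at 0.03.

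The last comparison asked which levels depended on the quantification program. Agreement between the programs varied from gene to gene, and of 127 named genes 78 differed by more than the SD between replicates. Named here after their values were seen, genes with similar levels were Tnf at 436 TPM by the alignment-based and 421 TPM by the alignment-free program, Acod1 at 1158 and 1061, Tnip3 at 653 and 623 and Nfkb1 at 488 and 473. Larger gaps were seen for Ccl5 (832 and 1097 TPM), Ccl4 (214 and 409), Nfkbia (301 and 439), Il1b (169.8 and 236), Cxcl10 (208.9 and 135), Atf3 (61.8 and 113), Nos2 (12.3 and 29.95), Tnip1 (226 and 419), Lgals3 (123 and 631) and Timeless (4.52 and 35.9). Further gaps over 1.5-fold included those of Irak2 (233 and 380.3 TPM), Tirap (2.79 and 6.87), Fcer1g (125 and 241), Hk3 (329 and 498), Ikbke (1390 and 2104) and Top2a (2.23 and 5.01). Levels were lower by the alignment-free program for H2-K1 (1661 and 1018), Rpl10 (92.2 and 59.5), mt-Atp8 (175 and 53.3), mt-Nd6 (66.7 and 41.3) and Gm23925 (365 and 23.3). Olfactory and vomeronasal receptor genes, which encode receptors of sensory neurons, summed to 3276 and 3945 counts by the alignment-based program and to 203181 and 202034 by the alignment-free one. At 1 TPM in both libraries were 13 of these 1481 genes by the first program and 390 by the second.

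Over 55450 genes given by both programs, Pearson's r of log2(TPM + 1) was 0.807 and Spearman's rho 0.746, and over protein-coding genes at 1 TPM by the alignment-based program they were 0.939 and 0.927. Of 20699 genes at 1 TPM by either program, 10657 differed by over 2-fold, 10374 of them higher by the alignment-free program. No counts in either library were given by the alignment-based program for 4914 genes at 1 TPM by the other. Among genes at 10 TPM or more by the first program, those furthest apart were the U3 copies Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 (454 ± 210 TPM each against 0.230), Snora43 (0 and 2.5 counts), the pseudogenes Gm10222 (66.1 ± 3.78 TPM against 0) and Gm10925 (56.4 ± 17.3 against 0.0045), and Gm25820, Gm27761 and Gm27640, each with under 3 counts per library.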

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

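Reads outside the annotated genes were recorded for 3 kinds of entry, each above the 3 counts that a count of 0 allows, with no control samples to compare. The phiX174 entry, a bacteriophage genome often added to sequencing runs as a control, held 56195 counts in replicate 1 and 46346 in replicate 2, or 0.305% (Wilson interval 0.302 to 0.307) and 0.262% (0.260 to 0.264) of all expected counts. Numbered entries without gene names held 21 and 14 counts. Entries of the ERCC spike-in mix had 0 counts by the alignment-based program in both libraries and 32 and 60 estimated counts by the alignment-free one. No outlier rule applied to a group of 2.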

How the results depend on the processing

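Directions of the list shifts outside the random range held under every alternative run, while the small medians of the TLR4 pathway and identity lists and of nuclear long noncoding RNAs changed sign and the balance of genes over 2-fold turned with library size. By the alignment-free program 19112 genes were detected in place of 11567, r between replicates was 0.981, protein-coding genes held 53.5% and small structured RNAs 0.912% of counts, retained-intron isoforms 33.8% of TPM, and 1 list in place of 2 lay at or below the 2.5th percentile in shift. With random lists from all protein-coding genes, 14 lists were high and 0 low in level. Replicate r was 0.972 with a pseudocount of 0.1, 0.936 at a mean TPM of at least 1 and 0.988 over protein-coding genes. Genes over 2-fold apart numbered 3096 with at least 1 count and 276 with at least 100. Against the common dispersion 34 genes differed, and 63 by the alignment-free program, whose exact binomial count was 966 in place of 904. The BCV was 0.283 from DESeq2's fitted dispersions and 0.247 with no filter. By TPM, protein-coding genes held 26.9%, the chromosome 17 interval 11.9% and small structured RNAs 55.2%, and by counts retained-intron isoforms held 25.0%. Between programs r was 0.784 with a pseudocount of 0.1 and 0.900 at a mean TPM of at least 1, where 2793 genes were over 2-fold apart. Among genes at 1 TPM by either program, 10657 were, and 8727 after division by the median ratio of 1.28, an alternative chosen after seeing the data. The other program's counts between replicates, 1074 genes over 2-fold among them, were also added then. Leaving out each replicate gave 56.9 to 58.5% for protein-coding counts, 22.8 to 27.7% for the chromosome 17 interval, 37.5 to 37.9% for retained introns, and 8 to 9 high lists. With TPM over protein-coding genes alone, 18 of 22 list medians and 115 of 127 named TPM values moved by more than their SD. All values of a library are then multiplied by the same factor, and percentiles move mainly through the 1 TPM limit for random lists. Of 44 named genes over 2-fold apart, 10 were under 2-fold by the other program and 4 with library size.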

Other observations

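Gene families picked after the data were examined, some of which share members with the preset lists, differed in level. Of 31 SR and hnRNP splicing factor genes, 30 reached 1 TPM in both libraries at a median of 65.3 TPM, above all 10000 random lists, with Hnrnpa2b1 at 799.7 ± 70.6 TPM, Srsf5 at 699.9 ± 115 and Srsf11 at 322 ± 69.7. The Gbp and Oas families, which hold genes of the interferon list, were high. The 10 guanylate-binding protein genes had a median of 82.5 TPM, with Gbp6 at 274 ± 86.5, and the 11 oligoadenylate synthetase genes 53.4 TPM, with Oasl2 at 852 ± 271. The 8 Schlafen genes had 65.0 TPM, led by Slfn8 at 264 ± 38.4, and the 12 Parp genes 42.3 TPM, Parp9 at 154 ± 23.5 among them. Antigen presentation genes were divided, with the MHC class I family at a median of 29.0 TPM (H2-D1 at 663 ± 51.7) and the class II gene H2-Ab1 at 9.44 ± 0.170 TPM, H2-Aa at 4.55 ± 0.106. Of 12 Toll-like receptor genes, Tlr4 of the TLR4 pathway list included, 9 reached 1 TPM in both libraries, Tlr1 highest at 209 ± 30.5 and Tlr2 at 51.5 ± 19.9 TPM. Replication-dependent histone genes had a median of 0.375 TPM over 67 genes, 9 of them at 1 TPM, and the 68 Trim genes a median of 1.33 TPM although Trim30a reached 245.7 ± 35.96.

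The tests in this and the next paragraphs were chosen after the patterns had been seen. Cytokine and chemokine genes shifted toward replicate 2 by a median log2 ratio 0.83 above that of macrophage identity genes (95% bootstrap interval 0.30 to 1.30, 24 and 20 members). Bootstrap intervals here cover the spread over genes within these 2 libraries, not the spread between replicates. The cytokine and chemokine lists were those with the largest shifts. After a cubic trend on GC content and transcript length was removed, which explained 1.79% of the variance, the gap was 0.75 (0.26 to 1.18), which argues against that trend as the whole cause. A smaller carry-over of mature RNA in replicate 2 was neither shown nor excluded. In 7 identity genes, reads of retained-intron isoforms had a median ratio of 0.0735 (-0.47 to 0.45). Reads of their coding isoforms, which such a change would lower, had 0.25 (-0.04 to 0.41). The gap on retained-intron reads was 0.41 (-0.26 to 1.84) against 9 cytokine and chemokine genes. Adgre1, Itgam and Fcgr1, the identity genes over 2-fold lower in replicate 2, had no retained-intron value and could not be tested. Values that go with a smaller carry-over were the mitochondrially encoded list (-0.43), Malat1 (0.46, with 7.96% and 10.4% of counts) and Rn7sk (1.04). Malat1 and Rn7sk are single members of lists that were not set apart. Nuclear long noncoding RNAs had -0.12 with 6 members above and 7 below 0, Neat1 at 0.18 and Xist at 0.20. Nuclear structural RNAs had 0.11 with 5 above and 4 below. Other values did not go with a smaller carry-over: cytosolic ribosomal proteins had -0.01, mt-Rnr1 1.04, and the signal recognition particle RNAs Rn7s1 and Rn7s2 0.67 each. The ribosomal protein list is weak evidence here. By the alignment-free program it had -0.12 at percentile 5.23, and retained-intron isoforms took 54.0% of its TPM. The chromosome 17 interval (27.7% and 22.8% of counts) lay mostly on Gm26917, outside the annotated ribosomal RNA gene, and was not read either way. The 250 and 500 ng of starting RNA and a difference in restimulation between cultures stay open as well, and with 1 condition no biological explanation was tested.

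Genes with reads from the alignment-free program alone, 3678 with at least 10 estimated counts, were set against as many genes on which the programs agreed at similar counts. Their median share of 31-mers found in transcripts of at least 10 other genes was higher by 0.427 percentage points (0.389 to 0.493), and 64.6% against 27.5% had any such 31-mer, so reads of repeated sequence may be placed on part of them. Overlap with an opposite-strand gene holding at least as many reads was less frequent, 6.69% against 26.0%, a difference of -19.3 points (-20.9 to -17.8). Most of these genes thus had no such annotated partner, and for the 6.69% antisense reads stay open. The difference itself does not decide the question, since the comparison genes were matched on counts alone and not on class or surroundings. Reads of partners were also taken from the alignment-based program, which gave lower totals. Copies such as the pseudogenes Gm12895 and Gm12896, each with 41654 and 23514 estimated counts, had no 31-mer of that kind, so repeats in many genes leave part of these genes open.

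Among the 15 mitochondrially encoded genes, mt-Co2, mt-Atp6 and mt-Nd4l were listed at 0 by the alignment-based program beside neighbours such as mt-Co1 with 5048 and 2864 counts. At least 98.9% of the 31-mers of each of these 3 genes occurred in transcripts of other genes, against a median of 10.5% in the 12 genes with reads in either library. Of those 12, mt-Co3 (99.9%, 1.63 and 0.54 counts) lay above that value and mt-Nd3 (98.1%, 57.0 and 0 counts) close to it, while the 10 genes with at least 10 counts in both libraries reached at most 63.9%. Reads shared with near-identical copies were therefore neither shown nor excluded as the cause by that test, and levels of these 5 genes are uncertain. Between the programs, reads were placed differently. The alignment-free program gave mt-Atp6 592 and 359 counts and mt-Nd4l 102 and 94. To the pseudogenes Gm10925 and Gm10222 it gave 0.11 and 0.0095, and 0 and 0. By the alignment-based program these pseudogenes had 494 and 300, and 80 and 77. Such values go with shared reads, but which genes share 31-mers with these pseudogenes was not tested.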
